A study of Homo sapiens with 8 samples.

How the data were processed

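Primary uterine leiomyoma cells of 4 donors were transfected with an siRNA against PLIN2 or with a non-targeting siRNA, each at 100 nM, and RNA was taken after 72 h. Per the labels' protocols the siRNA complexes were left on the cells for 5 h, a starvation medium was used from 24 h onward, and the libraries were made from total RNA with a stranded kit that removes ribosomal RNA. The authors deposited 1 table of raw read counts per gene for each of the 8 libraries, with gene symbols and no normalization. Per the submitters' processing notes, cutadapt 1.13, STAR, HTSeq 0.6.1p1 and DESeq2 were used, and the builds hg19 and mm10 are named. The role of mm10, the strand setting of the counting and the annotation used are not given in the sources used here. Reads that fall on overlapping or antisense genes, pseudogenes or near-identical copies can therefore be split or lost in ways that cannot be traced here.

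Libraries were grouped by the siRNA in their titles, 4 with control siRNA and 4 with PLIN2 siRNA. The replicate number in the titles stands for the donor. The 2 labels for the cell type disagree, since titles and protocols call all cultures leiomyoma while the cell type label calls the cultures of replicates 1 and 2 myometrial. The total counts were 16965234, 17565297, 15729630 and 19691477 in control replicates 1 to 4 and 17559413, 14710649, 16776485 and 13903441 in the PLIN2 siRNA replicates. No row of the tables lacked a gene name. Of 25369 symbols 21538 matched the GENCODE annotation of GRCh37 directly, 1487 through an older symbol and 2344 not at all. Coordinates and 3' UTR sequences were taken from that annotation.

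The counts were tested with edgeR 4.0.16 in R 4.3.3 (TMM scaling, the default low-count filter by group, robust quasi-likelihood fit, Benjamini-Hochberg adjustment at an FDR of 0.05), which left 14278 genes. The design chosen before the data were examined, together with the gene lists, the rule for named genes and most of the alternatives, compared the 2 siRNAs without a donor term and had the replicate number as a block as an alternative. Libraries of the same number deviated together from their group means, with correlations across genes of 0.80, 0.82, 0.92 and 0.79, while libraries of different numbers correlated at 0.13 at most, and the number is tied to the donor by the labels. Blocked values are therefore printed beside the others. In 2 further comparisons, the interaction of the siRNA with the cell type label was tested over all 8 libraries, and the 4 control libraries were compared by that label. No 2 libraries matched within sampling noise: chi-square per degree of freedom was at least 60.2 within groups and at least 15.4 between libraries of the same number.

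Preset gene lists, 41 in number, were tested with camera (limma 3.58.1, a preset correlation of 0.01, at least 5 measured members), which compares a list with all other genes, and with an estimated correlation and fry as alternatives. The mitochondrially encoded transcripts had 0 measured members, which left 40 lists. Named genes were the perilipins; the 12 largest rises and falls past FDR 0.05 with the same sign in all 4 donors and a mean of at least 1 CPM in a group, taken from the blocked fit where the unblocked one gave too few; up to 4 members per list with the smallest p in the blocked fit; and up to 5 rises and 5 falls in the comparisons by cell type label, of which none passed. Other genes are named where a list had few calls or where a gene stood out, and those were chosen after their values were seen. Genes of the X inactivation centre, Y-linked genes, HLA genes and symbols without an established name were left out, and a few other genes are not reported here. CPM values use TMM-scaled library sizes, and log2 ratios per donor use a prior count of 2.

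The share of PLIN2 that remained is the ratio of CPM values within a donor, with a 95% interval from the exact binomial (Clopper-Pearson) interval of the 2 counts. Reads are not independent molecules, so these intervals cover counting error only. To look for words shared by the genes that changed, the 3' UTRs of 13100 genes were scanned for all 16384 words of 7 bases, with 3' UTR length and GC content as covariates. A planted word came out lowest in 10 of 10 simulated runs, and shuffled fold changes gave t values between −4.67 and 4.51.

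The tests were tried on simulated data with the real means, library sizes and donors, 14278 genes and 100 genes changed at each size. At log2 changes of 0.5 and 1 edgeR without the block recovered 0% and 23%, and with the block 61% and 97%, with 24 unchanged genes called, 13.2% of the calls over both sizes. DESeq2 1.42.0, on the 14146 genes that passed the filter in the simulated counts, recovered 4% and 58% without the block and 45% and 91% with it, with 18 unchanged genes called in the latter. For lists, camera called the raised list in 10 of 10 runs with each design and 0.1 and 0.2 unchanged lists per run. In the real libraries, with the siRNA labels swapped within some donors, camera called 3 to 7 lists without the block and 4 to 10 with it. Uneven swaps leave part of the siRNA effect in the contrast. Swaps that divide the donors evenly cancel its mean, though not differences between donors. They gave 6, 4 and 4 lists without the block and 7, 4 and 8 with it. The simulated rates therefore cannot be taken as the error rate of the list calls.

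Alternatives were DESeq2 size factors in place of TMM, no low-count filter, a filter of 1 CPM in 4 libraries, DESeq2, limma-voom, the fit without robust estimation, a term for the cell type label, and each library or each donor left out in turn. Chosen after seeing the data were, all with the block, a correction for GC content and transcript length, library totals in place of TMM, thinning to the smallest library, a count among genes without CCTCTC in the 3' UTR, and fits within each cell type label, as well as DESeq2 with the block for the interaction. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the sequence scan, tables and figures.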

Results

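The series profiled primary uterine leiomyoma cells, cultured from the benign smooth muscle tumours known as fibroids, by sequencing of ribosomal RNA-depleted RNA after knockdown of PLIN2. PLIN2 encodes perilipin 2, a protein that coats cytoplasmic lipid droplets. Cells were transfected with 100 nM of an siRNA against PLIN2 or with a non-targeting control siRNA and were lysed after 72 h. There were 8 libraries, 4 per siRNA, and libraries with the same replicate number came from the same donor. The titles and protocols call all cells leiomyoma cells, whereas the cell type labels call replicates 1 and 2 myometrial and replicates 3 and 4 leiomyoma; both labels are treated as given. Total counts per library lay between 13903441 and 19691477, and 14278 of 25369 genes had enough counts to be tested.

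PLIN2 was lower with PLIN2 siRNA than with control siRNA in each of the 4 donors. The gene lies at chromosome 9, 19108373 to 19149288 on the minus strand (GRCh37). Its level was 38.4, 56.5, 7.77 and 154 CPM in control replicates 1 to 4 and 5.17, 7.59, 0.885 and 42.8 CPM in the PLIN2 siRNA libraries of the same numbers. The share that remained was 13.5%, 13.4%, 11.4% and 27.7%, on average 16.5% ± 7.55 (SD, n = 4). Counting error alone gave a 95% interval of 25.4 to 30.3% for replicate 4, above the widest of the other intervals, 6.18 to 19.6% for replicate 3, which contains those of replicates 1 and 2. Control levels differed more between donors than the knockdown changed them, and without a donor term the change did not pass the test (log2 fold change −2.19, adjusted p = 0.649, edgeR's quasi-likelihood test). With the replicate number as a block it did (log2 fold change −2.50 ± 0.21 (SE), adjusted p = 0.000401, edgeR). A two-sided exact permutation test of 4 against 4 libraries gave p = 0.114, where 0.0286 is the smallest p possible, and exact sign flips of the 4 pairs gave p = 0.125, which is their smallest. PLIN3 fell slightly in the blocked fit (log2 fold change −0.23, adjusted p = 0.0276, edgeR), PLIN4 had a log2 fold change of −0.03, and PLIN1 and PLIN5 had at most 9 counts in any library.

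**Figure D1:**
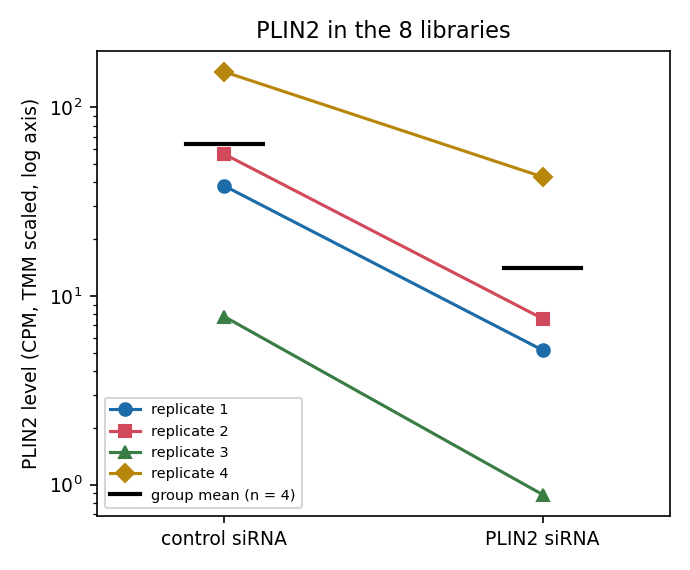
PLIN2 level in CPM after TMM scaling (log axis) in the 4 control siRNA and the 4 PLIN2 siRNA libraries; lines join libraries of the same donor and black bars are group means. Every line falls, from between 7.77 and 154 CPM to between 0.885 and 42.8 CPM.

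The first comparison asks which genes differ between cells with PLIN2 siRNA and cells with control siRNA. A call can reflect loss of PLIN2 or another effect of the siRNA, which 1 siRNA cannot separate. With the donor taken into account, 2862 genes passed FDR 0.05, of which 1219 rose and 1643 fell, and 2751 of them moved the same way in all 4 donors. The selection favours this agreement, since the fit used these same pairs. Most changes were small: 48 genes rose and 141 fell by more than 2-fold. Without the block edgeR called 0 genes, with 1428 at an unadjusted p under 0.05 and a lowest adjusted p of 0.0993, while DESeq2 called 500 (127 rose, 373 fell) without the block and 2185 (819 rose, 1366 fell) with it. All 2134 genes that both tools called with the block, from the same counts, had the same sign in both. With the pair of replicate 1, 2, 3 or 4 left out, the blocked edgeR fit called 1643, 2162, 1716 or 2963 genes, and with library totals in place of TMM it called 3271, of which 2119 rose and 1152 fell. Donors accounted for 84.2% of the variance between libraries. Here and below, rose and fell mean past FDR 0.05 in edgeR's fit with the replicate block. None of these genes passed in the fit without it. In simulated data with 100 genes changed at each size, unchanged genes made up 13.2% of the blocked fit's calls, above the FDR of 0.05. That share depends on how many genes change, so it does not give the share of false calls among the 2862.

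Among the largest rises were the receptor tyrosine kinase MET and its ligand HGF. MET increased from 34.0 to 103 CPM (log2 fold change 1.65 ± 0.12 (SE), adjusted p = 5.55e-05, edgeR) and HGF from 2.63 to 7.44 CPM (1.47 ± 0.19, adjusted p = 0.000199). The citron kinase CIT, which acts in cytokinesis, increased from 28.5 to 79.6 CPM (1.45 ± 0.08). The rises also held the growth factor BMP4 (1.76), the metallothionein MT1F (1.67), the tyrosine kinase TEC (1.45) and the nuclear protein MYEF2 (1.44). ARHGAP28 (1.36), CDC42BPG (1.38), GKAP1 (1.39) and GPR137C (1.46) rose as well, and CSMD3 rose by 2.60 from a mean of only 0.194 CPM. BMP4, MT1F, GPR137C, TEC, GKAP1 and CDC42BPG stayed under 2 CPM in both group means, and reads of MT1F can be shared with other metallothionein genes. ARHGAP28 stood at 14.0 CPM with control and 39.7 CPM with PLIN2 siRNA in replicate 3. In the other donors it was at most 1.30 and 1.89 CPM. Of these 12 genes only TEC (a 7-mer) and MYEF2 (a 6-mer) had a match to CCTCTC words in the 3' UTR, described next.

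The 12 largest falls, PLIN2 aside, included ADAM19, JAM3, MYD88 and FTL. ADAM19, a metalloprotease, decreased from 955 to 294 CPM (log2 fold change −1.88 ± 0.19 (SE), adjusted p = 0.00165, edgeR), the junctional adhesion molecule JAM3 from 81.5 to 20.4 CPM (−2.09 ± 0.34), and MYD88, the adaptor of Toll-like and interleukin-1 receptors, from 33.2 to 10.7 CPM (−1.74 ± 0.29). FTL, the ferritin light chain, decreased from 3482 to 1175 CPM (−1.70 ± 0.36, adjusted p = 0.0431), although its processed pseudogenes could take part of its reads. The falls also held the netrin receptor UNC5A (−2.22), the interleukin-15 receptor chain IL15RA (−1.76), the protocadherin PCDH19 (−1.80), NKAIN1 (−2.11), TPRG1L (−2.01), GRINA (−1.71), KANK4 (−1.70) and FAM167A (−1.69). Each of these 12 genes carried the 6 bases CCTCTC in its annotated 3' UTR, within a 7- or 8-base word (ACCTCTC, CCTCTCA or both) in 11 of them. Over all searched genes, such a 7- or 8-base word was present in 71.7% of the 138 genes with a 3' UTR that fell more than 2-fold and in 22.7% of the 13100 genes searched, and the 6 bases CCTCTC in 88.4% and 43.8%. These words occur in the PLIN2 mRNA as well. Pairing of the PLIN2 siRNA with such words may account for part of the falls, as described further below. The words were picked by a scan of these same fold changes, so their excess among the falls is not separate support for it.

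**Figure D2:**
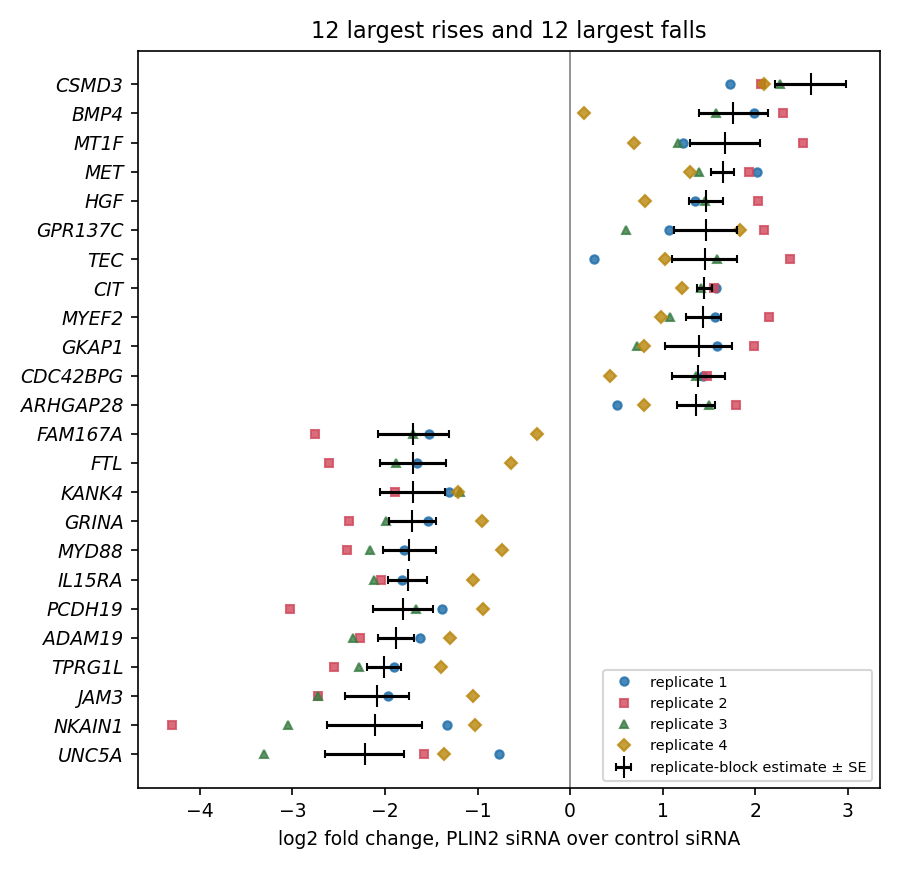
Log2 fold changes (PLIN2 siRNA over control siRNA) of the 12 largest rises and 12 largest falls; coloured points are the 4 donors, computed with a prior count of 2 that draws low genes toward 0 (CSMD3's estimate lies beyond its points), and black bars are the replicate-block estimates ± SE. As the rule for naming required, all points of a gene lie on the same side of 0. The estimates run from 2.60 (CSMD3) to −2.22 (UNC5A).

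Mitotic genes rose together. Of 40 measured genes of the G2/M and mitosis list 36 rose and 0 fell, with a median log2 fold change of 0.67. MKI67, the proliferation marker, increased from 157 to 247 CPM (0.67 ± 0.06 (SE)), the anaphase activator CDC20 from 37.0 to 66.8 CPM (0.85 ± 0.08), the kinesin KIF20A from 26.2 to 49.2 CPM (0.91 ± 0.09) and the centromere protein CENPF from 70.3 to 132 CPM (0.96 ± 0.09). The median was above 0 in each of the 4 donors (0.84, 0.49, 0.57 and 0.81), and with the pair of any donor left out 30 to 36 members rose. Adjusted over the list alone, 37 members passed with the block and 24 without it. The set test camera called the list (adjusted p = 4.62e-29 without the block), whereas adjusted p = 0.797 with an estimated correlation, or 0.512 with the block. The directional test fry called it as higher with the block (adjusted p = 0.0438) and not without it (0.375). Of the 36 genes 5 had a CCTCTC match in the 3' UTR.

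Part of the genes of DNA replication also rose, with a lower list median than the mitotic genes. Of 38 members of the G1/S and DNA replication list 16 rose and 0 fell (median 0.30), among them thymidylate synthase TYMS (0.74 ± 0.09), the helicase subunit MCM7 (0.43 ± 0.07), GINS3 (0.81 ± 0.16) and the polymerase subunit POLA1 (0.47 ± 0.10). Adjusted over the list alone 24 passed. Of 23 replication-dependent histone genes 8 rose (median 0.39), such as HIST1H1D (0.64) and HIST1H3A (0.60), and 11 passed adjusted over the list alone; near-identical histone copies can share reads. Camera without the block called both lists (adjusted p = 1.87e-08 and 1.74e-05), but adjusted p = 0.890 with an estimated correlation for each. Replicate 2 had the lowest medians, 0.01 and −0.12. The histone medians of replicates 1, 3 and 4 were 0.31, 0.68 and 0.66, so both myometrial-labelled cultures lay below both leiomyoma-labelled ones. With the pairs of replicates 1 to 4 left out in turn, 6, 25, 8 and 9 members of the replication list and 4, 20, 6 and 5 histone genes rose. Markers of leukocytes were higher in the same libraries, with a median of 0.38, as given below.

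A few genes of each lipid list changed, in both directions. Of 16 measured lipid droplet proteins METTL7A (0.80) and ACSL3 (0.27) rose and FITM2 (−0.60), PLIN3 (−0.23) and TMEM159 (−0.33) fell. Among 13 genes of lipolysis the lysosomal acid lipase LIPA increased from 45.5 to 75.8 CPM (0.74 ± 0.09 (SE), adjusted p = 0.000199, edgeR) and the hormone-sensitive lipase LIPE (0.54) and CES1 (0.43) also rose. In the same list monoacylglycerol lipase MGLL (−0.77 ± 0.10) and the triglyceride lipase PNPLA2 (−0.34 ± 0.07) fell. In glycerolipid synthesis the acyltransferases GPAM (−0.75) and AGPAT1 (−0.41) and the phosphatidate phosphatase LPIN2 (−0.63) fell, and AGPAT5, LPIN1 and CDS2 rose (0.46, 0.40 and 0.34). In cholesterol synthesis SREBF2 (−0.37), MSMO1 (−0.48) and SQLE (−0.30) fell and LSS (0.40) rose, out of 24. In fatty acid synthesis ACSS2 (−0.40), SLC25A1 (−0.24) and SCD (−0.23) fell and FADS1 (0.32) rose, out of 21. In fatty acid oxidation 5 of 24 genes fell, including CPT1A (−0.29), CPT1C (−0.31), ECHS1 (−0.41) and ETFB (−0.28), and EHHADH (0.50) and HSD17B10 (0.40) rose. The lipid droplet, lipolysis, glycerolipid, cholesterol, fatty acid synthesis and oxidation lists had 6, 5, 10, 4, 4 and 8 calls adjusted over the list alone. Their medians lay between −0.06 and 0.04 with TMM scaling, and those of the cholesterol and oxidation lists turned positive with library totals (0.02 and 0.05). The balance of calls depended on the scaling: with library totals the lipid droplet, cholesterol, fatty acid synthesis and oxidation lists had 3, 4, 5 and 3 rises and 1, 3, 1 and 2 falls. With a correction for GC content and length 6 cholesterol genes fell and 2 rose. Camera called none of them (lowest adjusted p = 0.634 without and 0.572 with the block), whereas the directional test fry with the block called the cholesterol list as lower (adjusted p = 0.0438). Of the named genes that fell, PLIN3, FITM2, TMEM159, MGLL, PNPLA2, GPAM, AGPAT1, LPIN2, SREBF2, ACSS2, SLC25A1, SCD, CPT1A, CPT1C and ECHS1 had a CCTCTC match in the 3' UTR, MSMO1 and SQLE had none, and ETFB was not searched.

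Part of the contractile and matrix genes fell with PLIN2 siRNA. Of 27 measured smooth muscle contractile genes 12 fell and 0 rose (median −0.12), including leiomodin LMOD1 (−0.36 ± 0.06 (SE)), tropomyosin TPM2 (−0.43 ± 0.07), the calcium channel CACNA1C (−0.52 ± 0.09) and the coactivator MYOCD (−0.53 ± 0.11). Of 30 matrix remodelling enzymes 9 fell and MMP9 rose (median −0.19). The collagen crosslinking enzymes LOXL1 (−1.17 ± 0.10), LOXL2 (−1.04 ± 0.11) and LOXL4 (−0.82 ± 0.07) and the procollagen protease ADAMTS2 (−0.82 ± 0.08) fell. Of 25 collagens 8 fell and 0 rose, while 10 had positive log2 fold changes, and the most abundant of the named ones were COL1A1, from 32671 to 22404 CPM (−0.53 ± 0.09), and COL6A1, from 3974 to 1912 CPM (−1.12 ± 0.12). Of 24 TGF-beta response genes 9 fell and SMAD6 and TGFBR2 rose (median −0.17), with TGFBR1 at −0.95, CTGF at −0.53 and PMEPA1 at −0.51. Of 20 YAP/TAZ targets, which share the falls of CTGF and TGFB2 with that list, 9 fell and LATS2 and PTPN14 rose (median −0.21), with AXL at −0.56 and IGFBP3 at −0.42. In these lists 12 contractile genes, 12 enzymes, 8 collagens, 15 TGF-beta genes and 11 YAP/TAZ genes passed adjusted over the list alone.

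Camera called the contractile, remodelling, TGF-beta and YAP/TAZ lists with the block (adjusted p = 0.0110, 1.13e-05, 0.000581 and 0.00421) but not without it (0.350 and 0.0704 for each of the other 3), and not the collagens (0.0543 with the block). With an estimated correlation and the block adjusted p = 0.698 for the contractile list, 0.512 for remodelling and TGF-beta, and 0.559 for YAP/TAZ. The directional test fry with the block called the remodelling, TGF-beta and YAP/TAZ lists as lower (adjusted p = 0.0464, 0.0438 and 0.0438). It did not call the contractile list (0.0643), and without the block it called none of them. With library totals in place of TMM 5 contractile genes and 5 collagens fell and 2 and 1 rose, with the pair of replicate 1 or 3 left out 7 or 6 contractile genes, 5 TGF-beta genes each and 4 or 5 YAP/TAZ targets fell, and with a correction for GC content and length 4 collagens fell and 3 rose. A CCTCTC match in the 3' UTR was present in 6 of the 12 contractile genes that fell, 6 of 9 remodelling enzymes, 5 of 8 collagens, 5 of 9 TGF-beta genes and 6 of 9 YAP/TAZ targets. It was present in 43.8% of all genes searched, 78.3% of all genes that fell and a mean of 51.0% in sets matched to those. LMOD1, LOXL1, CTGF and IGFBP3 had none. Members without a match had medians of −0.10 (contractile), −0.15 (remodelling), 0.04 (collagens), −0.22 (TGF-beta) and −0.12 (YAP/TAZ). The median of all searched genes without one was 0.06. CCTCTC was picked from these same fold changes, which favours higher values in genes without it.

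**Figure D3:**
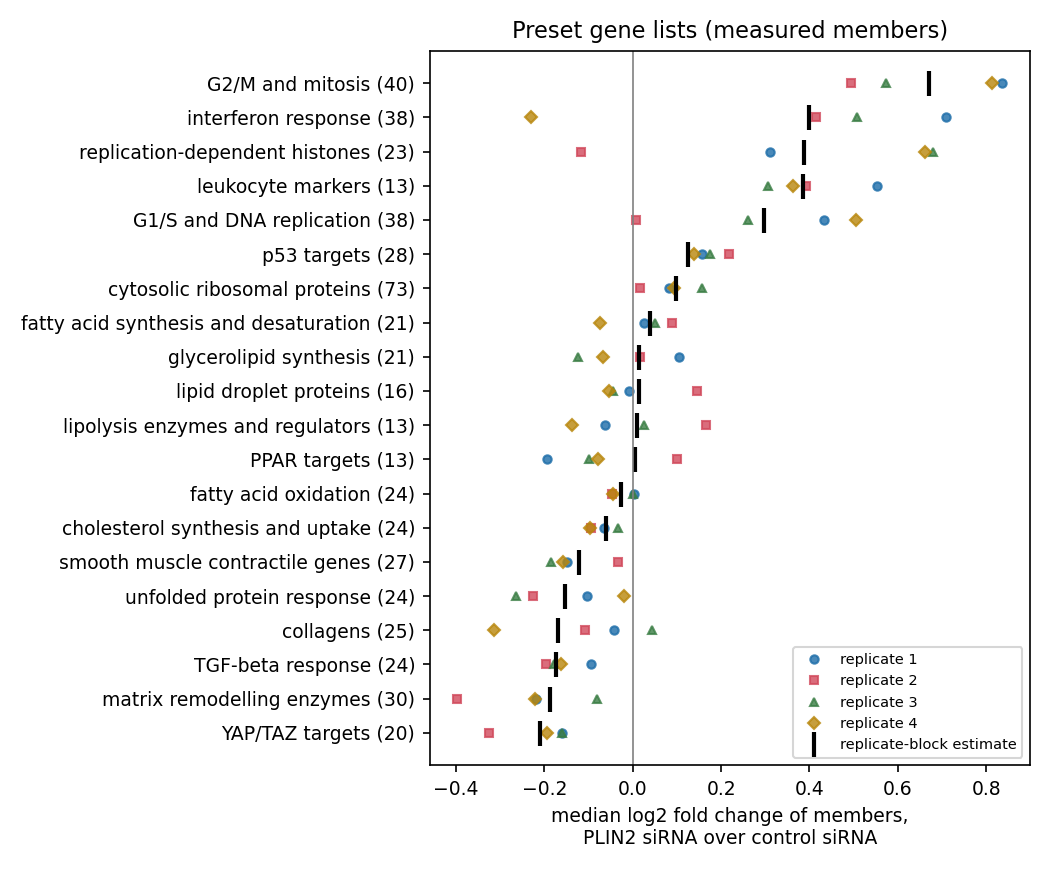
Median log2 fold change (PLIN2 siRNA over control siRNA) of 20 preset gene lists in each donor (coloured points) and in the replicate-block fit (black bars), with the number of measured members in brackets. The G2/M list is highest at 0.67 and the YAP/TAZ list lowest at −0.21, while the lipid lists lie between −0.06 and 0.04 with TMM scaling; in the interferon list replicate 4 stands at −0.23, opposite to the others.

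Genes of the unfolded protein response fell in part. Of 24 members 9 fell and PDIA4 and SEL1L rose (median −0.15), and HERPUD1 (−0.69 ± 0.08 (SE)), HYOU1 (−0.54 ± 0.07), EDEM1 (−0.73 ± 0.09) and the transcription factor XBP1 (−0.71 ± 0.09) led by p. Adjusted over the list alone 11 passed, and with the pair of replicate 1, 2 or 3 left out, or with library totals, 6 fell. Camera called the list without the block (adjusted p = 0.00809), but adjusted p = 0.890 with an estimated correlation, and 7 of the 9 genes, not XBP1, had a CCTCTC match. The 10 members without a match had a median of 0.03, with 2 falls and 1 rise, beside 0.06 for all searched genes without one. CCTCTC was picked from these same fold changes, which favours higher values in genes without it. Of 28 p53 targets 13 rose and 3 fell (18 adjusted over the list alone), and 8, 8, 7 and 11 rose with the pairs of replicates 1 to 4 left out in turn. SESN1 (1.11 ± 0.15), BBC3 (0.90 ± 0.13) and ZMAT3 (0.50 ± 0.08) rose. The cell cycle inhibitor CDKN1A (−1.38 ± 0.17, from 824 to 308 CPM) and TNFRSF10B (−0.60 ± 0.07) were among those that fell, each with a CCTCTC match; CDKN1A was singled out after its values were seen. Camera called this list with the block (adjusted p = 0.0420, or 0.744 with an estimated correlation) and not without it (0.105).

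Of 38 interferon response genes the RNA sensors DDX58 (0.62 ± 0.13 (SE)) and IFIH1 (0.76) and the induced genes IFIT2 (0.52), IFIT3 (0.64) and HERC5 (0.62) rose and IRF1 (−0.32) fell, with a median of 0.40 and 4 calls adjusted over the list alone. The list was not uniform across donors. Its median was 0.71, 0.42 and 0.51 in replicates 1 to 3 and −0.23 in replicate 4. With the pairs of replicates 1 to 4 left out in turn, 0, 3, 1 and 19 members rose, and with a correction for GC content and length 3 rose and 0 fell. Camera called it without the block (adjusted p = 0.000152, or 0.890 with an estimated correlation). Of 73 cytosolic ribosomal protein genes RPS15A, RPS24 and RPL34 rose (0.26, 0.21 and 0.22) and 0 passed adjusted over the list alone. Camera called this list as well (adjusted p = 0.00396, or 0.948 with an estimated correlation), and with library totals 27 members rose. Many of these genes have processed pseudogenes that could take part of their reads.

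Hormone-related and inflammatory genes changed in both directions. The progesterone receptor PGR (−0.45 ± 0.09 (SE)), the growth factor IGF1 (−1.14 ± 0.23) and the insulin receptor substrate IRS1 (−0.49 ± 0.07) fell and the steroid-induced FKBP5 (0.45 ± 0.08) rose. In that list 6 of 22 genes fell and FKBP5 and ESR1 rose, whereas 5 rose both with library totals (6 fell) and with the GC and length correction (7 fell). Of 24 cytokine and NF-kB genes 6 fell, with TNFAIP6 at −1.11 ± 0.15 and TNFAIP2 at −0.60 ± 0.10, and SOD2 and NFKB1 rose. PGR, IGF1, IRS1, TNFAIP6 and TNFAIP2 each had an 8-base ACCTCTCA match in the 3' UTR. Members without CCTCTC had medians of 0.07 in the hormone list and 0.004 in the cytokine list, with 0 and 4 falls. Adjusted over the list alone 12 and 8 genes passed, and camera called neither list (adjusted p = 0.810 and 0.527 without, 0.462 and 0.267 with the block). The directional test fry with the block called the hormone list as lower (adjusted p = 0.0438).

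Markers of other cell types were checked alongside. Of 13 leukocyte markers 6 rose and 0 fell (median 0.38, 7 adjusted over the list alone), namely C1QC (from 4.70 to 7.84 CPM, 0.86 ± 0.17 (SE)), C1QB (0.75), CD14 (0.71), LYZ (0.46), CD68 (0.38) and CD74 (0.35). Camera called the list with the block (adjusted p = 0.00278, or 0.512 with an estimated correlation) and not without it (0.105), and with the pair of replicate 1 or 3 left out 3 or 2 markers rose. The directional test fry called it as higher with the block (adjusted p = 0.0122) and not without it (0.876). Of 10 endothelial markers 0 passed edgeR's test with the block, over all genes or adjusted over the list alone; VWF, TEK, EGFL7 and TIE1 had an unadjusted p under 0.05, with log2 fold changes of −0.59, 0.38, 0.35 and −0.60. With library totals 2 of them passed. KRT7 fell among 7 epithelial markers, NOTCH3 fell among 8 pericyte markers and LIPE rose among 5 adipocyte markers. Of 13 fibroblast markers LUM (0.39), FAP (0.27) and S100A4 (0.56) rose and THY1 (−0.38) and PDGFRA (−0.34) fell, but with the GC and length correction 0 rose and 2 fell.

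The second comparison asks whether the knockdown acted differently in cultures labelled leiomyoma and myometrial, with 2 donors each. The interaction gave 0 genes in edgeR with 33 at an unadjusted p under 0.05, and 0 with the replicate block with 728 at an unadjusted p under 0.05 and a lowest adjusted p of 0.227. DESeq2 also called 0 genes with and without the block. Among the smallest unadjusted p with the block were histone genes such as HIST1H2BO, HIST1H4B and HIST1H2AG. Their log2 fold changes were higher in leiomyoma-labelled cultures by 1.02, 0.83 and 0.88, and none passed FDR 0.05. In simulated data with the same 14278 genes and 8 libraries, the test without the block found 0 of 100 genes whose effect differed by a log2 of 2, and the test with the block found 99. At an effect difference of a log2 of 1 these tests found 0 and 68. The test with the block also called 39 unchanged genes, 18.9% of its calls over both sizes.

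The third comparison asks how control cultures with the 2 labels differed. edgeR called 0 of 14364 genes between the leiomyoma-labelled and myometrial-labelled control libraries, with 918 at an unadjusted p under 0.05 and a lowest adjusted p of 0.762, and DESeq2 called 244 (168 higher and 76 lower in leiomyoma-labelled cultures). In simulated data edgeR found 57 of 100 genes changed by a log2 of 2 and 93 of 100 changed by 4. The simulation ran on 14278 genes, and 21 unchanged genes were called beside the changed ones. No gene passed the rule for naming in this comparison.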

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

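The values below come from groups of 4 libraries in which the highest or lowest lay far from the other 3, measured as its gap to the nearest of them divided by the range of all 4. Of 359 groups tested 30 passed the limit for that share. For independent groups of normally distributed values chance alone passes about 5%, or 17.95 groups. Most groups held CPM values that were not log-transformed, and both siRNA groups hold the same 4 donors, so that number is only a rough reference. The share of PLIN2 that remained passed with 0.873, since replicate 4 kept 27.7% and the others 11.4% to 13.5%. The PLIN2 level in the PLIN2 siRNA group passed with 0.840, with replicate 4 at 42.8 CPM and the others at 7.59 CPM or less.

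Replicate 3 stood highest in both groups for FABP3 (0.944 with control and 0.971 with PLIN2 siRNA), FABP4 (0.970 and 0.934), ARHGAP28 (0.924 and 0.966) and PGR (0.942 and 0.847). PGR was at 168 CPM in control replicate 3 and at most 48.6 CPM in the other controls. The same replicate was highest among controls for GKAP1 (0.908), JAM3 (0.947), MYLIP (0.960), BOK (0.902) and SFRP1 (0.841), lowest among controls for LOXL2 (0.905), and highest among PLIN2 siRNA libraries for TYMS (0.891) and LUM (0.958).

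Replicate 1 was highest for ANKRD37 in both groups (0.970 and 0.877) and for RPS7 with PLIN2 siRNA (0.984), and lowest for MCM7 among controls (0.832). Replicate 2 was highest for CDC42BPG among controls (0.942) and for METTL7A (0.855) and ABCC3 (0.945) with PLIN2 siRNA. Replicate 4 was highest for IFIT3 (0.863) and CD14 (0.833) among controls and for ANGPTL4 (0.845) and GINS3 (0.900) with PLIN2 siRNA, and lowest for EGFL7 with PLIN2 siRNA (0.832).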

How the results depend on the processing

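The alternatives with a correction for GC content and length, library totals, thinning, genes without CCTCTC and fits within a cell type label were chosen after seeing the data; so was DESeq2 with the block for the interaction. Without a donor term edgeR called 0 genes with DESeq2 size factors, no filter, the 1 CPM filter, no robust estimation, limma-voom in its place or a cell label term, and DESeq2 called 500. Pairing the libraries by replicate number as a block gave 2862 genes, and 2185 with DESeq2. With the block the count was 2957 with no filter, 2867 with DESeq2 size factors, 2963 after the GC and length correction, 2721 after thinning and 3271 with library totals. With library totals 2119 genes rose and 1152 fell, against 1219 and 1643 with TMM, so the share that fell was 35.2% in place of 57.4%; the totals leave out the scaling that TMM applies. Genes without CCTCTC gave 1190 calls, of which 841 rose and 349 fell, so that most rose where most of all calls fell. CCTCTC was picked from these same fold changes, which favours such a shift. The myometrial-labelled cultures gave 2042 calls and the leiomyoma-labelled ones 1497. With the pairs of replicates 1 to 4 left out in turn the block gave 1643, 2162, 1716 and 2963 genes, and with 1 library left out 1662 to 2959. Without the block, leaving out 1 library gave 0 to 106 genes; the 106 came without PLIN2 siRNA replicate 4, and the cause was not tested.

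The log2 fold change of PLIN2 passed in each blocked fit: −2.50 (edgeR), −2.66 (DESeq2), −2.52 (no filter), −2.51 (DESeq2 size factors), −2.50 (GC and length correction), −2.42 (library totals), −2.50 (thinned), and −2.40, −2.33, −2.46 and −2.92 with replicates 1 to 4 left out. Its adjusted p in these fits lay between 2.29e-16 and 0.00834. Without the block it lay between −3.82 and −1.28 with 1 library left out and passed in none of these fits.

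Camera called 6 lists, 10 with no filter and 12 with the replicate block. With an estimated correlation it called 0 with and without the block, and fry called 0 without the block and 7 with it. These 7 were the G2/M and leukocyte lists as higher and the cholesterol, hormone, remodelling, TGF-beta and YAP/TAZ lists as lower. With 1 library left out 6 to 9 lists passed. The interaction gave 0 genes under every alternative run. The control comparison by cell label gave 244 genes with DESeq2 and 0 otherwise; where a library was left out in the comparisons by cell label, the lone library of a label was assumed to vary like the others.

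For genes named by the rule, 522 values under other settings kept their direction and side of the threshold and 178 passed it (153 with the block, 25 with DESeq2). With 1 library left out 1363 kept both, 6 passed and 31 changed sign, in 25 genes. The lowest and highest log2 fold changes of these, without the block, were −0.39 and 1.09 (ABCC3), −0.073 and 1.33 (ANKRD37), −1.46 and 4.04 (ARHGAP28), −0.061 and 1.81 (C1QC), −0.017 and 0.91 (CDKN1B), −0.42 and 1.47 (CEBPA), −0.64 and 0.0070 (CEBPB), −1.06 and 0.21 (EGR1), −2.08 and 2.82 (FABP3), −1.79 and 2.38 (FABP4), −0.027 and 0.57 (FAP), −0.83 and 0.017 (IGFBP3), −1.15 and 0.81 (KRT19), −1.41 and 0.56 (KRT7), −0.72 and 0.012 (LMOD1), −0.027 and 0.95 (LSS), −0.98 and 0.026 (MFAP4), −0.30 and 1.08 (MYLIP), −0.15 and 0.72 (PAX8), −0.44 and 0.000343 (PFKP), −1.11 and 0.22 (PGR), −0.78 and 0.57 (PLIN4), −0.86 and 0.032 (POSTN), −0.46 and 0.015 (SCD), and −1.62 and 0.31 (SFRP1). The adjusted p of the leukocyte list lay between 8.87e-06 and 0.956 and that of the contractile list between 0.000452 and 0.906, with a change of direction. Leaving out 1 library without the block sets the other library of that donor against the remaining donors; beyond that the cause was not tested. With the block no call on the interaction changed.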

Other observations

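Of the tests below, those on the GC and length correction, on the scaling and on GACGTA words were chosen only after the data had been seen. Several gene groups outside the account above changed in part with PLIN2 siRNA; rose and fell again mean past FDR 0.05 in edgeR's fit with the replicate block. Of 36 lysosome and autophagy genes 6 rose, among them the cholesterol transporter NPC1 (log2 fold change 0.40), the protease CTSD (0.31) and LIPA (0.74), and NEU1 and ATP6V0D1 fell (−0.33 and −0.32). Of 22 NRF2 targets 5 rose, with TXNRD1 at 0.35 and the aldo-keto reductase AKR1C3 at 1.25, and HMOX1, GCLC and FTL fell (−0.60, −0.44 and −1.70). Of 23 apoptosis regulators 8 rose, with BIRC5 at 0.77, BBC3 at 0.90 and BCL2L1 at 0.39, and BOK, BAK1 and CFLAR fell (−0.49, −0.50 and −0.27). Of 15 FOXO targets SESN1, CDKN1B and FBXO32 rose (1.11, 0.47 and 0.27) and KLF9 fell (−0.44). Of 39 other matrix proteins 8 fell, including CTGF, FMOD (−0.46), POSTN (−0.53) and MFAP4 (−0.45), and EFEMP1, LUM, ASPN and LAMA4 rose (0.47, 0.39, 0.83 and 0.23). With library totals in place of TMM the lysosome and NRF2 lists had 9 and 7 rises and 0 falls past FDR 0.05; this scaling moved the median of all genes only from 0.01 to 0.09, so the loss of a call need not be the loss of a decrease. With the GC and length correction 4 lysosome genes fell. Of the FOXO targets 6 rose under either of these alternatives. Adjusted over the list alone, these 5 lists had 8, 8, 13, 8 and 13 calls, and camera called none of them with or without the block (lowest adjusted p = 0.165).

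Few genes of energy metabolism passed the test. Of 76 nuclear oxidative phosphorylation subunits SDHC and ATP5D fell (−0.40 and −0.24), with 0 calls adjusted over the list alone. In the tricarboxylic acid cycle citrate synthase CS, PDHB and SDHC fell (−0.39, −0.39 and −0.40) and pyruvate carboxylase PC rose (0.69), out of 22. In glycolysis GPI and PFKP fell (−0.32 and −0.25) and SLC2A3 rose (0.38), out of 21. Of 19 hypoxia genes VEGFA and ADM fell (−0.76 and −0.35) and KDM3A and ANKRD37 rose (0.44 and 0.62). Of 27 ATF4 targets SHMT2, CEBPB and PHGDH fell (−1.18, −0.30 and −0.22) and NUPR1 rose (0.20). Of 29 immediate early genes 6 fell, with EGR1 at −0.48, EGR2 at −0.77 and IER3 at −0.35, and BTG2, JUND and DUSP5 rose (0.52, 0.33 and 0.39). Of 16 Wnt targets SFRP1, CCND1 and MYC fell (−0.63, −0.78 and −0.32) and BMP4 rose. Of 13 PPAR targets 2 fell, including CPT1A, and FABP3 rose (0.39), and of 8 LXR targets ABCA1 fell (−0.57). The balance of these calls depended on the scaling: with library totals the oxidative phosphorylation, tricarboxylic acid cycle, glycolysis, ATF4 and LXR lists had 3, 2, 4, 1 and 3 rises and 0, 2, 1, 1 and 1 falls. Camera called none of these 9 lists with or without the block (lowest adjusted p = 0.275), and adjusted over the list alone they had, in the order after oxidative phosphorylation, 4, 3, 4, 2, 10, 4, 3 and 4 calls.

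The falls of more than 2-fold may in part come from a seed match of the PLIN2 siRNA, that is, pairing of its bases 2 to 8 with 3' UTRs of other genes. Over all 7-base words in 3' UTRs the most negative t was that of ACCTCTC (−23.3, mean effect −0.21), and its size was 3.40 times that of the largest positive t. All 7 lowest words held CCTCTC, the 8-base word ACCTCTCA occurs in the PLIN2 coding sequence (exon 7, chromosome 9, 19118379 to 19118386, GRCh37), and 71.7% of the 138 genes with a 3' UTR that fell more than 2-fold had a 7- or 8-base match against 24.0% in matched sets. Among all 1609 genes with a 3' UTR that fell the shares were 54.1% and 27.2%. CCTCTC was picked from these same fold changes, so its excess among the falls is not separate support. A given word of 7 bases has a 10.9% chance of occurring in an mRNA of the length of PLIN2's. A bias of GC content or length is argued against, since after correction 98.6% of 140 such genes still fell past FDR 0.05. The sequence of the siRNA is not given in the sources used here, so the seed itself was not compared, and 16 of the falls of more than 2-fold had no match in the 3' UTR, 7 of which had a 7-base match in the coding sequence.

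Scaling moves all genes of a library alike, and the median of the G2/M list lay 0.66 above that of all genes, which argues against scaling as the cause of its rise. After the correction for GC content and length 35 members rose, which argues against that bias. Whether it follows from loss of PLIN2 or indirectly from genes lowered through the seed match cannot be told apart with 1 siRNA: 31 of the members that rose had no CCTCTC in the 3' UTR, which either would give. The cell cycle inhibitor CDKN1A, singled out after its values were seen, fell in 4 of 4 donors (log2 fold change −1.38) and has a 7-base match in its 3' UTR, and may be one such gene. A second siRNA against PLIN2 or a rescue was not analysed here.

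The words with the largest positive t held GACGTA in 4 of the 5 highest (6.85 for TGACGTA). Scanned by donor, a GACGTA word was highest in replicates 2 and 3 (t of 6.67 and 5.69). In replicates 1 and 4 the highest word was AGCTACT (5.59 and 5.35). A candidate explanation is a seed match of the control siRNA, relieved in the PLIN2 siRNA libraries; without its sequence this cannot be told apart from an effect of the knockdown.

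The count of genes without the block was 0 for the real split, so each of the 35 of 35 splits reached it and the comparison says nothing about chance; the highest other, 452, came from the split along the cell type label, in which donors and label cannot be told apart, and the 2 other splits that part no pair gave 6 and 165. At an unadjusted p under 0.05 the real split gave 1428 genes and the other 7 splits that part all pairs at most 224, while 6 splits that part fewer pairs gave more. For lists without the block chance was not excluded, since 30 of 35 splits gave as many as the real 6, the highest other being 15 in a split that parts 2 pairs. Among splits that part all pairs the other ones gave 3 to 7 lists without the block and 4 to 10 with it, where the real one gave 12. Those that swap the labels evenly between donors, so that the mean siRNA effect cancels, gave 6, 4 and 4 without the block and 7, 4 and 8 with it. With the block, only 1 of the 8 splits that part all pairs, the real one, called as many as 2862 genes and the highest other called 0, but 8 splits are too few for a share under 0.05. The other 7 reverse the siRNA labels in some donors. This cancels part or all of a shared siRNA effect and adds what is cancelled to the error. Their 0 calls are therefore no measure of the false calls among the 2862.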
